A study of Mus musculus with 16 samples.

How the data were processed

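Immunoprecipitated DNA from sonicated nuclei of primary bone-marrow macrophages was sequenced, per the labels' protocols, for EZH2 (untreated and nigericin after LPS), p53, H3K27ac, H3K27me3 and SIRT1 (Ezh2 wild type and knockout, p53 wild type and knockout). The labels give 16 samples, of which 9 are immunoprecipitations and 7 are inputs, with 1 library per group. Per the series' design text, each processed file was made from an immunoprecipitated and an input sample. Which input served which library is not stated beyond the labels' names.

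The deposited files are 9 peak lists in the narrowPeak layout of 10 columns, 1 list per library and none pooled. Per the submitters' processing notes, MACS2 and deepTools were used on the mouse build GRCm38/mm10, and the versions, the aligner and the read filters are not given in the sources used here. The names of the peaks in the deposited lists refer to a duplicate-marked alignment file. The deposited fold column holds the ratio of fragments at the summit to the local background, each with a pseudocount of 1. The deposited −log10 columns hold the p-value and the q-value of each peak as the authors' caller gave them. The deposited score column was found to be 10 times the −log10 q in the histone lists and 10 times the −log10 p in the others. From the values, the histone lists had been limited at a q of 0.05 and the EZH2, p53 and SIRT1 lists at a p of 0.01 with no limit on q, so most of their peaks have a q above 0.05 and their lengths move with the depth. Read totals are not given in the sources used here. The most common background of a list was 0.722 to 0.854 fragments for SIRT1, 1.95 for p53, 2.34 and 2.74 for EZH2 and 2.68 and 3.05 for the histone marks.

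Peaks on chromosomes 1 to 19, X and Y (21 chromosomes) were used. Coordinates are given 1-based. Genes came from a RefSeq table of the same build (GRCm38), with 49939 genes on these chromosomes, 21883 of them protein-coding. The table gives gene bounds without strand, exons or sequence, so the start of a gene could not be told from its end: in place of the planned windows around transcription starts, windows of 1 kb either side of both gene ends were used, and a peak called at a gene end overlapped one of them. The planned split into exons, introns and intergenic sequence and the planned search for the p53 motif were not run, since exon positions and a genome sequence were not used here.

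Peak lists were compared by the share of peaks of the first list overlapping the second by at least 1 bp, with its Wilson 95% interval, which covers counting error only. Chance was measured by 1000 circular shifts of 1 list within each chromosome (200 for the alternatives), giving a two-sided permutation p for the place of peaks within 1 pair of libraries, not for a difference between conditions. Shifts do not keep mappability or chromatin context. The number of genes in common for independent lists is the product of both counts over the number of genes. The share of summits within 1 kb of a gene end was measured likewise. For each of 14 gene lists fixed before the data were examined (inflammasome and pyroptosis, NF-kB and LPS response, type I interferon response, p53 targets, Polycomb developmental regulators, macrophage identity, sirtuin and NAD, Polycomb and H3K27 enzymes, long non-coding RNA, ribosomal proteins, and markers of neutrophils, lymphocytes, stroma and erythroid cells), the members with a peak at a gene end were counted and set beside 10000 random lists of the same size, as a description of 1 library with no p-value. A list was said to stand apart when fewer than 2.5% of random lists had as many or as few. Fragments at the summit were solved from fold and p-value under the Poisson model of the caller and came out whole to within 0.0001 of the −log10 p for at least 99.96% of the peaks of each list.

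The genes named were set by a rule fixed before the data were examined: 10 fixed genes (Neat1, Nlrp3, Cdkn1a, Mdm2, Trp53, Ezh2, Sirt1, Il1b, Casp1 and Gsdmd), the 10 genes with the highest peak fold at a gene end per list, for each pair of lists the 10 highest with no peak of the other list within 5 kb of the window, the 10 highest in both, and up to 4 members per gene list. Genes without a formal symbol were passed over, and some genes that the rule selects are not reported here. Peaks inside Nlrp3, near Cdkn1a and Fasl, list members beyond the first 4, and genes named only for their clusters or widths were chosen after their values were seen. The folds given for a gene in several lists are the highest at its ends in each list and can come from different peaks, unless overlap is stated. Ranks and folds from lists of different length do not measure change.

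Alternatives fixed before the data were examined were a −log10 q of at least 5, an overlap of 50% of the shorter peak, lists of equal length, exclusion of regions with a peak in all 9 lists, a window of 5 kb and random lists matched on H3K27ac. Alternatives chosen after seeing the data were a q of at most 0.05, at least 6 fragments for SIRT1, exclusion of regions with a peak in all 7 lists other than the histone marks, counting the whole gene, and random lists of protein-coding genes. The overlap measure was tested on simulated data, with errors of up to 0.699 percentage points over 6 simulated pairs, and 100% of 2682 simulated fragment counts were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Input libraries entered only through the authors' peak calls.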

Results

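Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on primary mouse macrophages, grown from C57BL/6 bone marrow for 5 days in medium with M-CSF, the growth factor of this lineage. Of the 16 samples, 9 were immunoprecipitated libraries with a peak list each and 7 were inputs. In wild-type cells, EZH2, the H3K27 methyltransferase of Polycomb repressive complex, was mapped in untreated macrophages and in macrophages given nigericin, a potassium ionophore that activates the NLRP3 inflammasome, after priming with LPS. The tumour suppressor p53 and the histone marks H3K27ac (active chromatin) and H3K27me3 (the product of EZH2) were mapped in untreated wild-type cells. The deacetylase SIRT1 was mapped in untreated Ezh2 wild-type, Ezh2 knockout, p53 wild-type and p53 knockout macrophages. Each group held 1 library (n = 1), so differences between conditions have no replicate check, and every interval given covers counting error only.

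On chromosomes 1 to 19, X and Y of GRCm38/mm10, the lists held 9771 EZH2 peaks in untreated cells, 5128 EZH2 peaks after nigericin and 5068 p53 peaks. H3K27ac had 51604 peaks covering 73.0 Mb and H3K27me3 had 88037 peaks covering 124 Mb. SIRT1 had 74767 peaks in Ezh2 wild-type, 18170 in Ezh2 knockout, 56323 in p53 wild-type and 59807 in p53 knockout macrophages. Total read numbers are not given in the sources used here, but the fragments at each summit could be recovered from the listed values. The weakest SIRT1 peaks rested on 3 fragments in 3 of the lists and on 4 in the Ezh2 knockout list, the weakest p53 peaks on 6, both EZH2 lists on 7 and both histone lists on 9. At a q-value of at most 0.05 there remained 1746 EZH2 peaks in untreated cells, 761 after nigericin and 59 for p53. For SIRT1 the same threshold left 249, 524, 180 and 323 peaks in Ezh2 wild-type, Ezh2 knockout, p53 wild-type and p53 knockout cells. The fold enrichment of a peak is the authors' own value and describes that peak within its list. Peaks at the targeted genes cannot check the deletions: the Ezh2 gene had no peak at either end in any list, and Trp53, which encodes p53, had an H3K27ac peak of 1.68-fold and a SIRT1 peak of 3.31-fold in the p53 knockout list.

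The first comparison asked where EZH2 lay in resting macrophages relative to its own mark. EZH2 sat at genes of embryonic patterning that carry H3K27me3. The highest EZH2 folds at gene ends, among genes with a formal symbol, were at Lbx1 (9.37), Hoxc9 (8.55), Neat1 (8.31), Rims2 (8.29), Foxi3 (8.20), Erfl (7.96), Foxd3 (7.83), Dmrta2 (7.78) and Gata6os (7.52), the last a transcript beside the endoderm factor gene Gata6. All of these but Neat1 also had an H3K27me3 peak, from 7.31-fold at Dmrta2 to 11.9-fold at Erfl. Of 35 developmental regulators chosen as Polycomb targets, 32 had an EZH2 peak and 35 had H3K27me3, against means of 1.75 and 7.25 in random gene lists. Examples were the homeobox genes Hoxa9 (EZH2 6.26, H3K27me3 12.2) and Hoxc13 (6.56 and 11.4), the neural factor gene Olig2 (7.17 and 13.3) and Gata6 (7.52 and 8.79). Tbx5, Isl1 and Bmp4 were the 3 members without EZH2 in untreated cells. Only 1 member, Lhx2, had an H3K27ac peak (3.25), against a mean of 6.20.

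Across all peaks, 4053 of the 9771 untreated EZH2 peaks (41.5%, Wilson 95% interval 40.5 to 42.5) overlapped H3K27me3. Circular shifts of the list along each chromosome gave 5.57% (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). The overlap with H3K27ac went the other way, with 212 peaks (2.17%, 1.90 to 2.48) against 3.97% from shifts (permutation p = 0.002). The share within H3K27me3 rose to 85.8% among EZH2 peaks with q of at most 0.05 and to 98.1% among the 376 with −log10 q of at least 5. At gene ends, 2079 of the 2475 genes with an EZH2 peak (84.0%) also had H3K27me3, and 136 had H3K27ac where independent lists would share 438. Genes with EZH2 and H3K27ac peaks included Fxyd7 (EZH2 4.50, H3K27ac 6.22), Osgin1 (4.44 and 3.99), the collagen gene Col4a2 (5.35 and 3.90), Dchs1 (4.95 and 3.84) and the POU factor gene Pou3f1 (3.64 and 7.36). Among the 10 such genes with the highest folds, all but Neat1 had H3K27me3 as well. Among Polycomb subunit genes, Bmi1, of a different Polycomb complex than EZH2, had EZH2 at 7.31-fold, H3K27me3 at 4.10 and H3K27ac at 3.0. Cbx8 had EZH2 at 5.66 and H3K27me3 at 10.7. Of the 22 Polycomb and H3K27 enzyme genes, 3 had EZH2 (random mean 1.09), 5 had H3K27me3 (4.57) and 12 had H3K27ac (3.89).

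**Figure D1:**
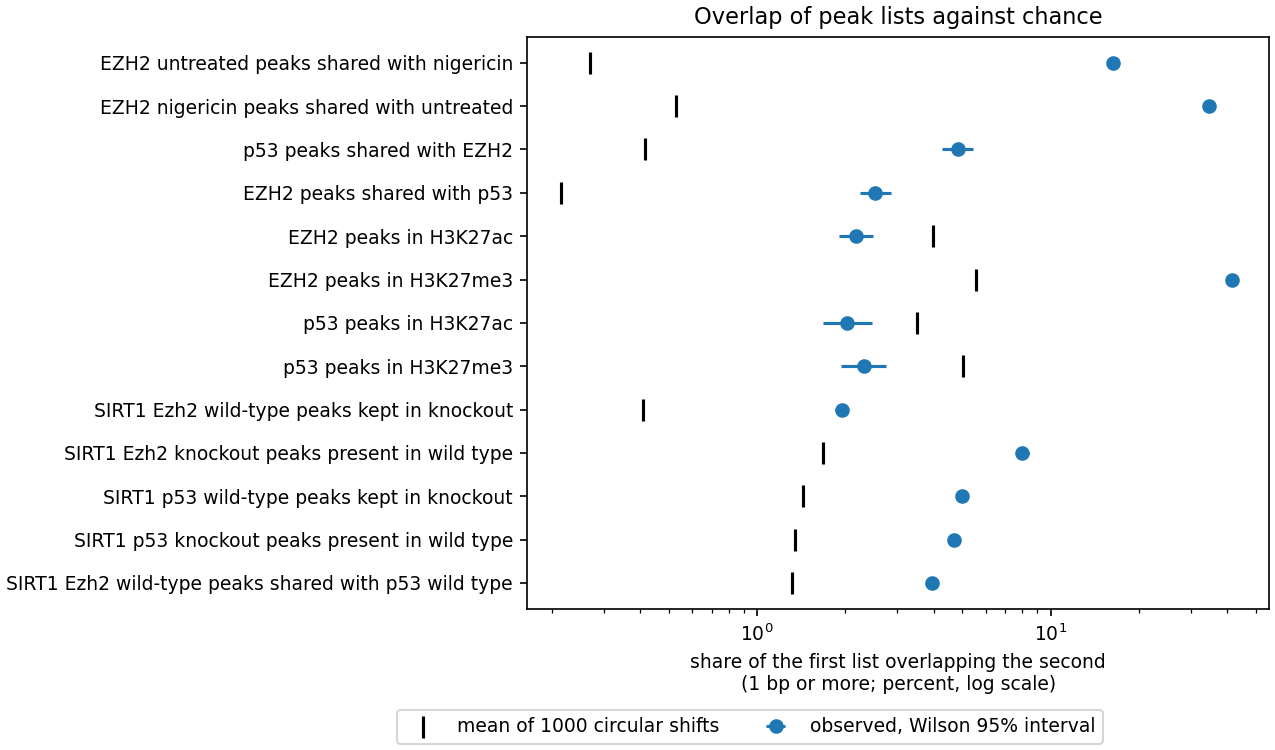
Percent of the peaks of the first list of each pair that overlap a peak of the second list (points, with Wilson 95% intervals) and the mean of 1000 circular shifts (vertical bars), on a log axis in percent. EZH2 peaks lay in H3K27me3 at 41.5% against 5.57% from shifts, and in H3K27ac at 2.17% against 3.97%.

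The second comparison asked how EZH2 peaks differed after LPS priming and nigericin. No library had LPS alone, so LPS and nigericin cannot be told apart, and the nigericin list stands for both. Most Polycomb target genes had EZH2 peaks in both lists, while several interferon-inducible genes had a peak in the nigericin list alone. The highest fold after nigericin at an end of a gene with a formal symbol was at Samd9l, an interferon-inducible gene (11.7, 38 fragments), which had no untreated peak within 5 kb of its ends. Gvin1, which encodes an interferon-inducible GTPase, followed at 10.2 and had only a peak of 2.41-fold (8 fragments) in untreated cells. The highest fold of the list, at a place without a formally named gene (chromosome 7, 106501912 to 106512499), was 14.1, and it overlapped an untreated peak of 3.74. Ifit1 (4.72) and Trim30d (4.49) were also in the nigericin list alone, and the neighbouring interferon genes Ifit2 and Ifit3 had nigericin peaks of 2.69 and 2.31, both with a −log10 q of 0. Of 20 type I interferon response genes, 3 had a nigericin EZH2 peak (1.70% of random lists had as many) and 0 had an untreated one. That count depended on the setting: 5.10% of random lists of protein-coding genes had as many, and 1 gene was left with q of at most 0.05. All 20 had H3K27ac and none had H3K27me3 in untreated cells. At Samd9l, Gvin1, Ifit1 and Ifit2 the highest EZH2 peak lay at the end of the gene that had no H3K27ac, with H3K27ac at the opposite end (3.84, 3.23, 3.79 and 2.13). Samd9l and Gvin1 also had a lower EZH2 peak at the end with H3K27ac (2.99 and 4.41), and at Ifit3 and Trim30d the highest EZH2 peak lay at an end with H3K27ac. In all, 8 nigericin peaks with −log10 q of at least 5 overlapped no untreated peak. Some lay at Samd9l, in Gvin1 and beside Gvin1 on chromosome 7. The others lay at the ribosomal RNA sequences Rn18s-rs5 (1.37, 559 fragments) and n-R5s146 (3.13, 46 fragments), at Pramel35 (5.68) and on chromosome 5 (15051630 to 15052093, 3.50).

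Other genes with EZH2 in the nigericin list alone were Ttll6 (4.41), Shroom3 and the zinc-finger factor gene Snai2 (4.19 each), the neighbours Optc and Prelp (3.89), the collagen gene Col4a3 (3.78) and Uaca (3.72), all of which had H3K27me3 in untreated cells. Genes with EZH2 in the untreated list alone were led by Hdgfl3 (6.59), the linker histone gene H1f10 (6.26), the synaptic gene Bsn (6.07), Ttc9 (5.94), the growth factor gene Fgf18 (5.89) and the collagen genes Col27a1, Col4a1 and Col4a2 (5.35 each). Genes with high EZH2 folds in both lists were Bmi1 (7.31 untreated, 6.18 nigericin), Olig2 (7.17, 5.96), Erfl (7.96, 5.67), Mmp24 (5.62, 5.38), Hoxc13 (6.56, 5.25) and Sox21 (7.17, 5.24), each from overlapping peaks. At Otp the untreated peak of 7.0 met a nigericin peak of 4.13, and another nigericin peak of 5.35 met an untreated peak of 3.29. At Hoxa13 untreated peaks of 5.57 and 4.79 met nigericin peaks of 3.51 and 5.38. At Gata4, a heart and endoderm factor gene, the nigericin peak of 7.48 overlapped an untreated peak of 4.95, while other untreated peaks there, of 6.17 and 5.82, met nigericin peaks of 2.56 and 4.02. Of the 35 Polycomb targets, 27 had an EZH2 peak after nigericin (random mean 1.01).

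By overlap, 1593 of 9771 untreated EZH2 peaks (16.3%, 15.6 to 17.0) met a nigericin peak, against 0.269% from shifts, and 1771 of 5128 nigericin peaks (34.5%, 33.2 to 35.8) met an untreated peak, against 0.528% (permutation p = 0.002 for both, the smallest possible). At gene ends, 1019 genes had EZH2 in both lists (71.2 for independent lists), 1456 in the untreated list alone and 417 in the nigericin list alone. The nigericin list was the shorter one, and with both lists at equal length the first share was 26.3%. With q of at most 0.05 in both lists, 56.5% of nigericin peaks met an untreated peak. Nigericin EZH2 peaks lay in untreated H3K27me3 at 52.6%, against 5.72% from shifts, and in H3K27ac at 4.13%, against 4.07% (permutation p = 0.865). The H3K27ac share with q of at most 0.05 in both lists was 1.45% against 5.04% (permutation p = 0.00995, the smallest that 200 shifts can give).

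The third comparison, set by interest in the lncRNA Neat1 and the inflammasome, asked whether EZH2 and p53 occupied the same places. Neat1, the long non-coding RNA that scaffolds nuclear paraspeckles (gene 66961, chromosome 19, 5824708 to 5845480), carried both. The untreated EZH2 peak at its upper-coordinate end spanned 5845395 to 5846324 (8.31-fold, 37 fragments), and the p53 peak spanned 5845435 to 5846265 (7.14-fold, 24 fragments). Both lay under an H3K27ac peak (5842728 to 5846446, 4.16-fold) and outside H3K27me3. After nigericin the EZH2 peak there had 2.82-fold and 11 fragments, with a −log10 q of 0.197. Nlrp3, which encodes the inflammasome sensor (gene 216799, chromosome 11, 59541569 to 59566955), had no EZH2 or p53 peak at its ends but had strong peaks of both within the gene. There the untreated EZH2 peak spanned 59548030 to 59549714 (6.26-fold, 40 fragments), the nigericin peak 59548026 to 59549614 (5.67-fold, 24 fragments) and the p53 peak 59548014 to 59549674 (9.33-fold, 41 fragments). An H3K27ac peak of 3.75-fold covered 59547901 to 59549712, and the nearest H3K27me3 peak lay beyond the gene (59570394 to 59572352, 5.72-fold). The edges of both Nlrp3 EZH2 peaks differed by 4 and 100 bp, a closeness reached by 1.48% of the 474 compared pairs of EZH2 peaks.

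**Figure D2:**
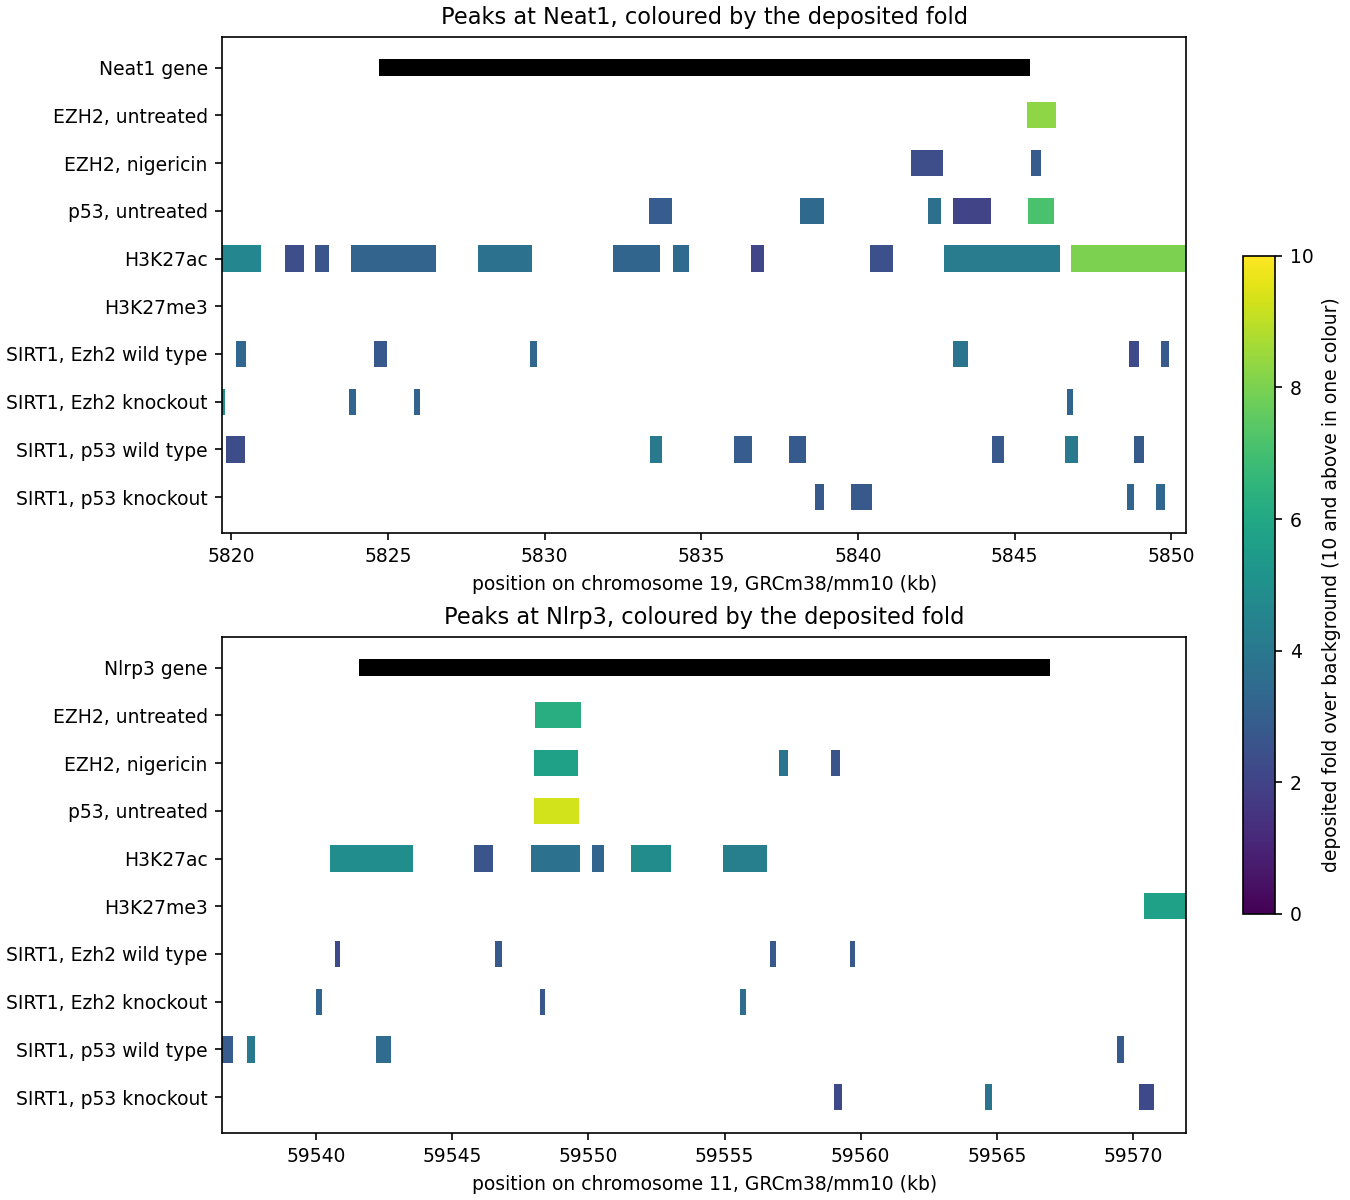
Peaks of the 9 lists along the Neat1 and Nlrp3 regions, with the position in GRCm38 on the horizontal axis in kb and 1 track per list, each bar spanning a peak and coloured by fold. At Neat1 the EZH2 peak (8.31) and p53 peak (7.14) lie at the same end of the gene, and at Nlrp3 the EZH2 peaks (6.26 and 5.67) and the p53 peak (9.33) share 1 place inside the gene.

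The Neat1 and Nlrp3 places differed from most strong EZH2 peaks in their chromatin. Of the 376 untreated EZH2 peaks with −log10 q of at least 5, 7 lay outside H3K27me3 and 3 lay over H3K27ac (Neat1, Nlrp3 and Bmi1), a description chosen after the values were seen. Of the same 376, 308 overlapped a nigericin peak, and the nigericin fold divided by the untreated fold had a median of 0.666 (quartiles 0.529 and 0.846). The ratio was 0.340 at Neat1, rank 8 from the lowest, and 0.906 at Nlrp3, rank 255. These peaks were selected on the untreated library, which by itself lowers such ratios. Of 89 nigericin peaks of the same strength, 81 had an untreated peak, with a median untreated to nigericin ratio of 0.888.

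**Figure D3:**
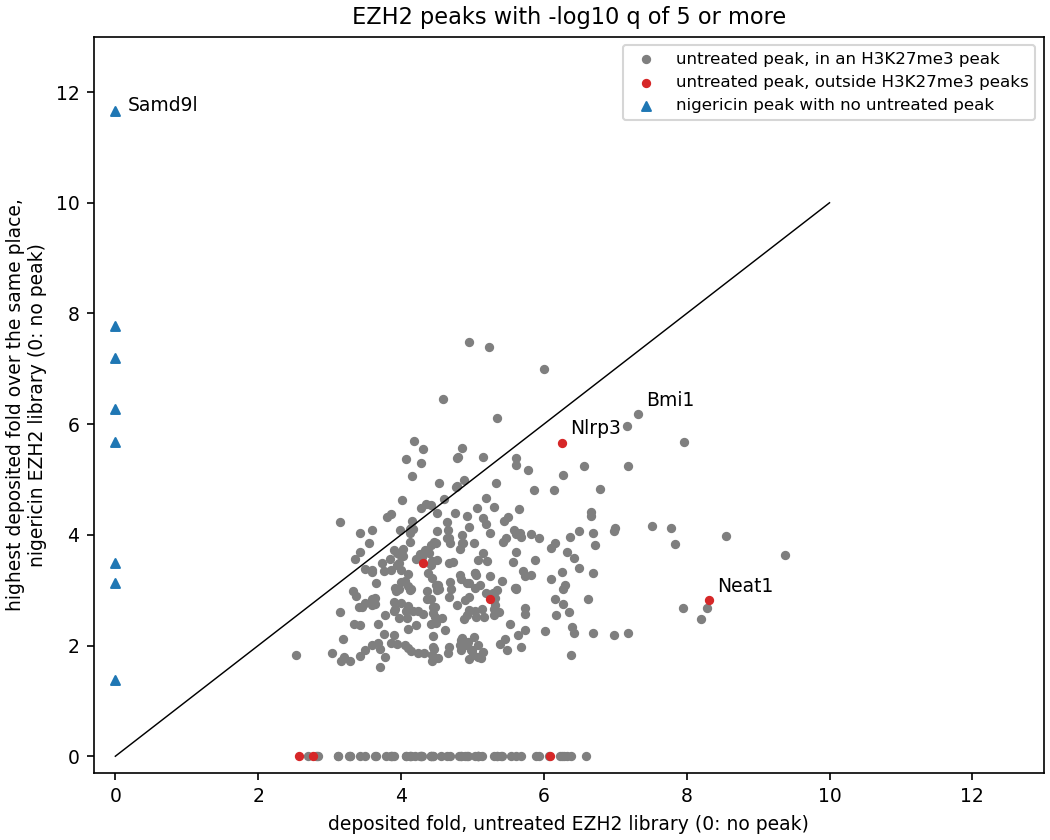
EZH2 fold enrichment in untreated cells (horizontal axis) against the nigericin library (vertical axis), in fold over background, with circles for the 376 strong untreated peaks (red outside H3K27me3, 0 where no peak met them), triangles for the 8 strong nigericin peaks with no untreated peak, and the line of equal folds. Among the 308 peaks with a partner the median ratio was 0.666, with Neat1 at 0.340 and Nlrp3 at 0.906.

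Other genes named for EZH2 and p53 peaks had lower folds. They were the zinc-finger genes Zfp981 (EZH2 3.21, p53 4.08), Zfp978 (2.88, 3.89), Zfp980 and Zfp534 (2.67 and 2.72 each), Pramel34 (3.18, 4.0) and the vomeronasal receptor genes Vmn1r2 (3.48, 2.72) and Vmn1r151 (2.94, 2.72). The zinc transporter gene Slc30a4 (4.30, 4.01) and Pgm5 (2.91, 2.86) also had both. A place without a formally named gene (chromosome 1, 24611605 to 24616120) had a p53 peak of 8.32-fold with 114 fragments and an EZH2 peak of 5.25-fold, outside H3K27me3, with peaks in 3 of the 4 SIRT1 lists. In total, 245 of 5068 p53 peaks (4.83%, 4.28 to 5.46) overlapped untreated EZH2, against 0.414% from shifts, and 247 of 9771 EZH2 peaks (2.53%, 2.23 to 2.86) overlapped p53, against 0.215% (permutation p = 0.002 for both, the smallest possible). The 245 shared p53 peaks also met SIRT1 peaks at 6.12% in the Ezh2 knockout, 4.90% in the p53 knockout, 4.08% in Ezh2 wild type and 3.27% in p53 wild type, against 0.850%, 1.22%, 1.95% and 1.62% of the 4823 other p53 peaks, and nigericin EZH2 at 22.4% against 1.33%, differences that were not tested. Of the 245 shared p53 peaks, 87 (35.5%) fell in the 5 densest megabases, led by the megabases from 147 Mb of chromosome 4 and from 20 Mb of chromosome 8 with 23 each. The megabase from 146 Mb of chromosome 4 held 18, and Zfp978 lay in that from 147 Mb. By the labels' names untreated EZH2 and p53 had the same input. Whether these clusters or a shared input account for the overlap was not tested. With q of at most 0.05 in both lists, 14 of 59 p53 peaks (23.7%) overlapped EZH2. At gene ends, 57 of the 363 genes with a p53 peak also had EZH2 (18 for independent lists). After nigericin, EZH2 overlapped 119 p53 peaks (2.35%, against 0.217% from shifts).

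The p53 library was next set against active and repressed chromatin and against known p53 targets. Few p53 target genes had a p53 peak: 2 of 31, the ribonucleotide reductase gene Rrm2b (3.06) and the kinase gene Plk2 (2.72), where 2.33% of random lists had as many. Neither peak had a q of at most 0.05. Counting the whole gene, 2 members had a peak and 30.5% of random lists had as many. Cdkn1a, which encodes the cell-cycle inhibitor p21, and Mdm2, the ubiquitin ligase gene that feeds back on p53, had no p53 peak at their ends. A p53 peak of 2.26-fold with 6 fragments lay near Cdkn1a on chromosome 17 (29101832 to 29102299), inside an H3K27me3 peak of 7.95-fold and overlapping a peak in each of the 4 SIRT1 lists. Nearby, a region (29107352 to 29107915) had a peak in all 7 lists other than the histone marks. The same 31 genes had H3K27ac at 17 members (mean 5.46), led by Xpc (5.57), Pidd1 (5.46), Aen (5.27) and Polk (5.15). H3K27me3 marked 4 (Perp 4.74, Eda2r 4.69, Tnfrsf10b 4.20 and Phlda3 3.46), and untreated EZH2 marked Perp (3.19) and Phlda3 (2.32).

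The highest p53 fold at a gene end was at Fasl, the death ligand gene (10.9, 31 fragments). Its pair of p53 peaks on chromosome 1 (161781584 to 161781965 and 161787950 to 161788287) were 382 and 338 bp long, and no other list had a peak there. Whether the pair reflects binding was not tested. Among genes with a formal symbol Neat1 followed, and then Zfp981, Slc30a4, Pramel34 and Zfp978, with Cep152, Vmn1r155 and Zfp936 at 3.74. Genes with p53 but no EZH2 nearby included Cytl1, Tas2r108, Vmn1r20, Chpt1, Vmp1 and Tcl1b3 (3.40 each) and the chemokine gene Ccl20 (3.06). Genes with p53 and H3K27ac were Vmp1 (p53 3.40, H3K27ac 4.75), Npepps (3.06, 5.98), Dcakd (3.06, 5.06), Nmt1 (3.06, 4.02) and Dnmt3aos (2.98, 8.89). Genes with p53 and H3K27me3 included Syt9 (3.0, 4.94), Pgm5 (2.86, 9.14) and Elmod1 (2.66, 6.42). Of the 363 genes with a p53 peak at an end, 29 had H3K27ac and 25 had H3K27me3. Independent lists would share 64.2 and 75.3. At a q of at most 0.05 only 11 genes kept a p53 peak, none of them those named here with H3K27ac or H3K27me3.

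In all, 103 of 5068 p53 peaks (2.03%, 1.68 to 2.46) overlapped H3K27ac, against 3.50% from shifts, and 117 (2.31%, 1.93 to 2.76) overlapped H3K27me3, against 5.03% (permutation p = 0.002 for both, the smallest possible). The H3K27ac result was not kept in 3 settings, of which the stricter ones left 11 and 59 p53 peaks: with −log10 q of at least 5 in both lists the share was 18.2% against 3.55% (permutation p = 0.149), and with q of at most 0.05 it was 5.08% against 4.57% (permutation p = 0.846). With lists of equal length it was 0.710% against 0.949% (permutation p = 0.139). The 18.2% came from the places at Neat1 and Nlrp3. Within 1 kb of a gene end lay 6.20% of p53 summits, where shifts gave 6.12% (permutation p = 0.851), against 21.6% for untreated EZH2, 24.2% for nigericin EZH2, 15.0% for H3K27ac and 10.7% for H3K27me3. The p53 share was 15.3% (9 of 59 peaks) with q of at most 0.05 (permutation p = 0.0299) and 36.4% (4 of 11) with −log10 q of at least 5 (permutation p = 0.0199). The latter 4 were 1 of the Fasl peaks, the Neat1 peak, a peak in Sfi1 (2.06-fold, 149 fragments) and the place on chromosome 1 (24611605 to 24616120). Several more of the 59 peaks were clustered in Sfi1 on chromosome 11 (3161018 to 3199913).

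The fourth comparison asked how SIRT1 occupancy differed without Ezh2. Few of all SIRT1 peaks met a peak of the other list in Ezh2 wild-type and knockout macrophages, and the strongest peaks did so most often. Genes with SIRT1 in both lists were Opn3 (wild type 4.40, knockout 5.39), the NF-kB inhibitor gene Nfkbie (4.95, 4.32), Btrc, a ubiquitin ligase subunit gene of the same pathway (4.95, 4.32), Rapgef3 and Ahnak (4.40, 4.32 each) and the neighbours Thap4 and the autophagy protease gene Atg4b (3.85, 4.32 each). The wild-type list alone had Rpl15 and its neighbour Nkiras1 (6.06), Cfap45, Atp6v0a2, Dnajc15 and Otulinl (4.95 each), R3hdm2 (4.50) and the chaperonin gene Cct6a (4.46). The knockout list alone had Tox4 (5.93), Teddm2 (5.64), Klf7 (5.42), the MHC gene H2-Q6 (5.04) and Hdlbp, Septin2, Mmp24, Erp29 and Arhgap25 (4.85 each). Also among the highest knockout folds were Mill2 and Selenos (5.93) and Nfe2l2, the oxidative stress regulator gene (5.39). None of these genes had more than 10 fragments at its SIRT1 summit.

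Rela, which encodes the NF-kB subunit p65, had the highest wild-type fold among the ends of the named genes (17.1, 44 fragments). Its peak on chromosome 19 (5646809 to 5647382) was 574 bp long, the other SIRT1 lists had no peak at that place, and an H3K27ac peak (5646785 to 5647282, 2.83-fold) overlapped it. Whether this peak reflects binding was not tested. Cdkn1a had 5.31 in the wild-type list, from the place near its end where the p53 list and all 4 SIRT1 lists had a peak. That place lay near a region with a peak in all 7 lists other than the histone marks. Of the p53 targets, 13 of 31 had SIRT1 in Ezh2 wild type (mean 5.82, 0.230% of random lists had as many) and 5 in the knockout. Ribosomal protein genes had 15 of 30 (mean 5.64) and 7 of 30 (mean 2.25), led by Rpl15 (6.06) and Rpl32 (4.14). Inflammasome and pyroptosis genes had 6 of 24 in each, with 0.620% of random lists having as many in the shorter knockout list. Ninj1 (wild type 3.85, knockout 2.46), Naip5 (2.75, 3.78) and Neat1 (2.75, 3.24) had a peak in both lists, Casp1 (3.30) in wild type but not the knockout, and Nlrc4 (3.78) and Gsdmd (2.66) in the knockout but not wild type. Sirtuin and NAD genes had 9 of 22 (mean 4.12) and 4 of 22. Matching random lists on H3K27ac at the gene ends left only the ribosomal genes in wild type apart from random (1.95% had as many). With q of at most 0.05, p53 targets had 1 gene in each list, ribosomal genes 1 in wild type and 0 in the knockout, and inflammasome and sirtuin genes 0 in both.

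By overlap, 1450 of 74767 wild-type SIRT1 peaks (1.94%, 1.84 to 2.04) met a knockout peak, against 0.408% from shifts, and 1455 of 18170 knockout peaks (8.01%, 7.62 to 8.41) met a wild-type peak, against 1.68% (permutation p = 0.002 for both, the smallest possible). Among the 48 and 43 peaks with −log10 q of at least 5 the shares were 47.9% and 55.8%, beside 50% of the Ezh2 wild-type peaks for the pair of wild-type libraries. Of these strong peaks 70.8% and 72.1% lay between genes, against 36.4% and 30.7% of all peaks. The difference in list length varied with the fragments at the summit. At the p threshold, 3 fragments over the most common background gave a −log10 p of 2.01 in wild type and 1.95 in the knockout, on either side of the limit of 2. With at least 4 fragments at the summit the lists held 56428 and 18170 peaks (0.322 times as many in the knockout), with at least 5 they held 23032 and 14372 (0.624 times) and with at least 6 they held 6330 and 7072 (1.12 times).

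**Figure D4:**
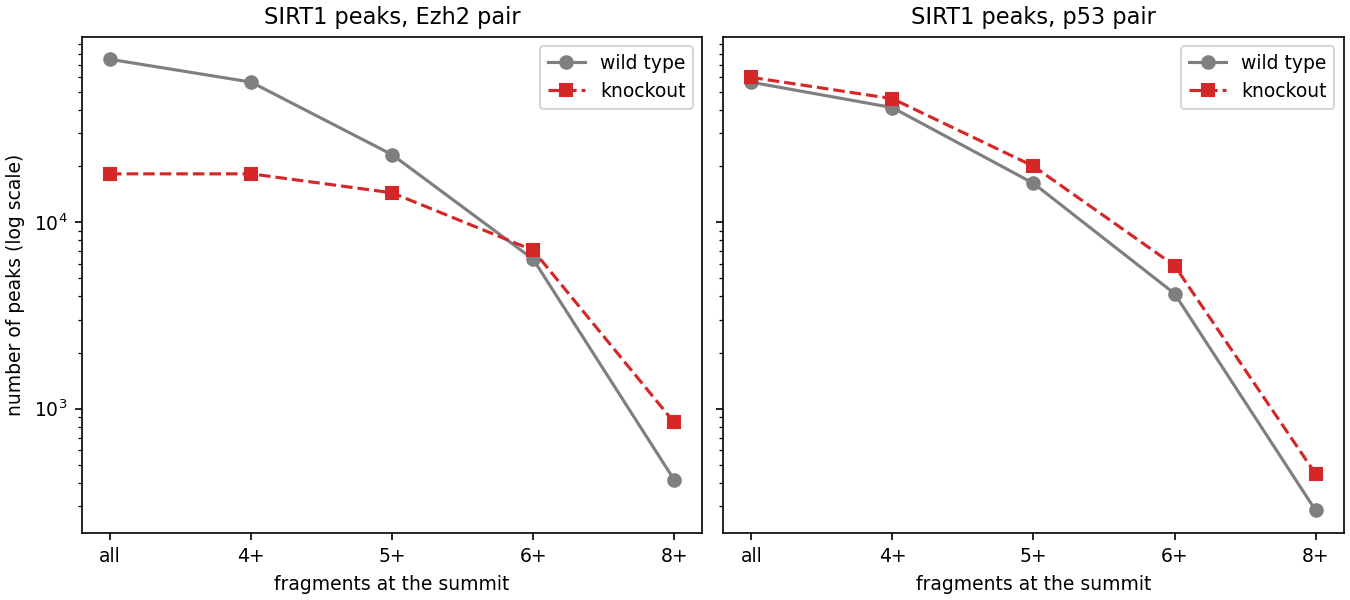
Number of SIRT1 peaks (vertical axis, log scale) by the least number of fragments at the summit (horizontal axis), in wild-type (grey circles) and knockout (red squares) lists of the Ezh2 pair and the p53 pair. The knockout to wild-type ratio is 0.243 over all peaks, 0.322 with at least 4 fragments and 1.12 with at least 6 for Ezh2, and 1.06, 1.12 and 1.41 for p53.

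The fifth comparison asked the same without p53. Genes with SIRT1 in p53 wild-type and knockout macrophages were Pilrb2 (wild type 4.65, knockout 5.35), the phosphate exporter gene Xpr1 (4.50, 6.07), Eef1akmt2 (4.50, 4.96), Btbd2 (4.65, 4.41), the chemokine gene Ccl2 (4.65, 4.41) and the GTPase gene Rhoc (3.94, 4.09). The wild-type list alone had Zfp606 (6.39), Arel1 (6.18), the tRNA-processing gene Trnt1 (5.81), the interleukin-6 receptor gene Il6ra (5.23), Camk1d (5.06), the phosphatase gene Ptpn2 (4.68) and Nit1, Slc20a2 and Sap30l (4.65 each). The knockout list alone had Wls, the Wnt secretion factor gene (6.02, 73 fragments), the neighbours Coa5 and Unc50, Cep170, Slc37a3, Tatdn2, Clec4g, Sdf2l1 and Plpp6 (4.96 each) and the NK and myeloid adaptor gene Hcst (4.82). At Wls, 73 fragments at that fold mean a local background far above the most common value of the list (0.813). Whether the Wls peak reflects binding was not tested. High knockout folds were also found at Gnai2 (5.89) and at the adhesion gene Icam1 and Ppp2ca (5.51 each).

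Macrophage identity genes had SIRT1 at 8 of 24 in p53 wild type and 13 of 24 in the knockout (mean 4.16, 0% of 10000 random lists had as many), led in the knockout by Tyrobp (4.82), Cd68 (4.41) and Spi1 (4.34). NF-kB and LPS response genes had 13 of 30 in both (means 5.18 and 5.27), interferon response genes 9 and 10 of 20 (3.45 and 3.48), p53 targets 14 and 13 of 31 (5.35 and 5.38) and ribosomal genes 15 and 11 of 30 (5.19 and 5.25). Inflammasome genes had 10 of 24 in wild type (4.15), among them Txnip (4.07), Nlrp3 (3.48) and P2rx7 (2.90), and 6 in the knockout. Long non-coding RNA genes had 10 of 20 in wild type (3.45) and 6 in the knockout. Polycomb targets had 10 of 35 in wild type and 1 in the knockout (6.10), and with at least 5 fragments 1 and 0. With random lists matched on H3K27ac, the wild-type counts of p53 targets (0.870% had as many), ribosomal genes (1.96%) and long non-coding RNA genes (0.630%) stayed apart from random, and none of the knockout counts named here did. With q of at most 0.05, none of these lists stood apart in either library.

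In all, 2802 of 56323 p53 wild-type SIRT1 peaks (4.97%, against 1.43% from shifts) met a knockout peak, and 2806 of 59807 knockout peaks (4.69%, against 1.35%) met a wild-type peak (permutation p = 0.002 for both, the smallest possible). At −log10 q of at least 5 the shares were 43.8% and 30.6%. Both wild-type SIRT1 libraries gave a measure of how far separate libraries without a deletion match: 2941 of 74767 Ezh2 wild-type peaks (3.93%, against 1.31%) met a p53 wild-type peak. They had in common Med12l (4.40 and 4.50), Ccdc17 (4.40 and 4.65), Btbd2 (4.40 and 4.65) and Sema4a (4.40 and 4.07). Selenov and Btrc (4.95 each) and Mgat5 and Celf2 (4.40 each) were in the Ezh2 wild-type list alone, and Fcf1 (6.18), Nfx1 and Vps29 (5.23 each) and Tmem165 (5.06) in the p53 wild-type list alone. Relative to shifts the wild-type pair shared 2.99 times as many, the p53 pair 3.48 times and the Ezh2 pair 4.75 times, and the difference between these ratios was not tested. The order changed with the setting: with at least 6 fragments in both lists the shares were 2.80% against 0.115% from shifts for the wild-type pair, 3.98% against 0.169% for the p53 pair and 3.59% against 0.180% for the Ezh2 pair.

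SIRT1 lay in active chromatin more often than shifted lists did, in all 4 libraries. Its peaks overlapped H3K27ac at 9.97% in Ezh2 wild type, 15.5% in Ezh2 knockout, 12.3% in p53 wild type and 13.3% in p53 knockout cells, and H3K27me3 at 8.46%, 9.51%, 8.94% and 7.76%, where shifts gave 3.54% to 3.59% and 4.86% to 4.94% (permutation p = 0.002 for all, the smallest possible). With q of at most 0.05 in both lists the H3K27ac overlap passed the threshold in all 4, while the H3K27me3 overlap no longer did in Ezh2 wild type (9.24%, permutation p = 0.0796), p53 wild type (9.44%, 0.139) and p53 knockout (7.74%, 0.249). Overlap with untreated EZH2 was 0.714%, 1.22%, 0.840% and 0.660%, where shifts gave 0.371% to 0.380%. Over all peaks, overlap with p53 passed the threshold in the Ezh2 knockout, at 0.308% against 0.133% from shifts (permutation p = 0.002), and was 0.143% in Ezh2 wild type (permutation p = 0.623), 0.153% in p53 wild type (0.406) and 0.120% in the p53 knockout (0.298). It passed in all 4 with q of at most 0.05 in both lists, at 2.01% in Ezh2 wild type, 0.382% in Ezh2 knockout, 1.67% in p53 wild type and 1.24% in the p53 knockout (permutation p = 0.00995 for each, the smallest that 200 shifts can give), from 5, 2, 3 and 4 SIRT1 peaks. These lay at only 4 places, and 3 of the places had a peak in at least 3 of the 4 SIRT1 lists. Among the 3 were chromosome 1 (24611605 to 24616120) and chromosome 2 (98666579 to 98667279). The p53 peak at the place on chromosome 2 was 1.39-fold, and its number of fragments could not be recovered. The share of SIRT1 summits within 1 kb of a gene end was 11%, 16.5%, 13.3% and 12.7% in the same order. At Neat1, SIRT1 peaks of 3 to 8 fragments were found in all 4 lists within 5 kb of the gene, and at its ends in every list but that of the p53 knockout. Sirt1 itself had H3K27ac (3.11) and no SIRT1 peak at its ends.

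H3K27ac in untreated macrophages marked the genes of the inflammasome, NF-kB and macrophage lists. Macrophage identity genes had H3K27ac at 23 of 24 (mean 4.24), led by Spi1, the lineage factor gene (10.8), the M-CSF receptor gene Csf1r (7.87), Maf (7.15) and Tyrobp (7.02), and only Cd36 lacked it at its ends. Inflammasome genes had it at 18 of 24 (4.27), with P2rx7 (6.23), Ninj1 (4.93), Nlrp3 (4.86), Il1a (4.83), Gsdmd (3.57), Casp1 (2.82) and Il1b (2.22), while the DNA sensor gene Aim2 had H3K27me3 (4.94). NF-kB and LPS genes had it at 24 of 30 (5.32), with Nfkb1 (7.77), Zfp36 (5.18), Ccl3 and Ccl4 (4.98 each) and Tnfaip3 (4.87), and 1 member, Nfkb2, had H3K27me3 (8.41). Ribosomal genes had H3K27ac at 26 of 30 (5.34) and sirtuin and NAD genes at 14 of 22 (3.88), with Parp2 (6.32), Pparg (5.35) and Sirt2 (5.24). Ppargc1a, a coactivator gene of mitochondrial biogenesis, instead had EZH2 (3.59) and H3K27me3 (5.92). Long non-coding RNA genes had H3K27ac at 9 of 20 (3.53), with Dleu2 (7.48) and Pvt1 (5.91), and H3K27me3 at 4, with H19 (7.66). H3K27me3 marked 0 macrophage, 0 interferon, 0 ribosomal and 1 NF-kB gene (random means 4.99, 4.17, 6.22 and 6.25).

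**Figure D5:**
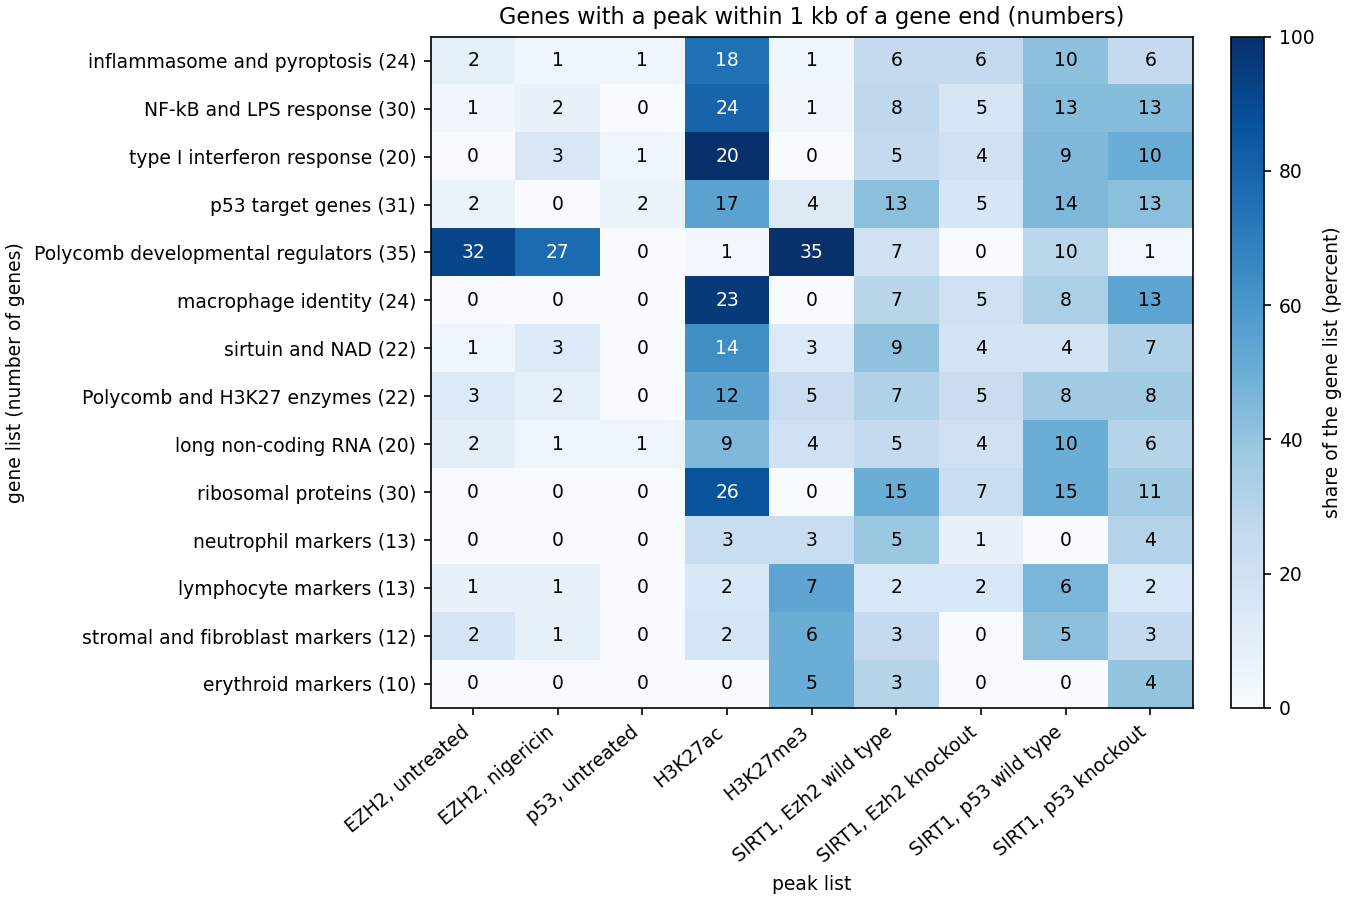
Number of genes of each gene list (vertical axis, list size in brackets) with a peak within 1 kb of a gene end in each of the 9 libraries (horizontal axis), shaded by percent of the list. Polycomb developmental regulators stand out for EZH2 (32 of 35) and H3K27me3 (35 of 35), and macrophage identity genes for H3K27ac (23 of 24).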

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

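The tests of explanations given here were all chosen after the results had been seen.

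The SIRT1 list of the Ezh2 knockout was 0.243 times as long as that of its wild type, while the p53 knockout list was 1.06 times as long as its own, and this difference in direction was not tested. The p threshold admitting 3 fragments in the wild-type list and 4 in the knockout list cannot be told apart from fewer places of SIRT1 enrichment in the knockout, since the ratio moved with the selection of peaks. It was 0.322 with at least 4 fragments, 0.624 with 5, 1.12 with 6, 2.03 with 8, 2.10 with q of at most 0.05 (524 against 249) and 0.896 with −log10 q of at least 5 (43 against 48), so that 2 of the 6 stricter selections were well under 1. The knockout list held fewer peaks of 4 fragments than of 5 (3798 and 7300), so a selection at 4 fragments need not remove the threshold. An effect of Ezh2 loss on SIRT1 binding remains open, with 1 library per genotype and no read totals used here.

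The EZH2 list after LPS and nigericin had peaks at 6 interferon-inducible genes (Samd9l, Gvin1, Ifit1, Ifit2, Ifit3 and Trim30d), of which Gvin1 also had an untreated peak (2.41-fold), and those at Ifit2 and Ifit3 had a −log10 q of 0. Signal at every highly active gene was argued against, as 0 of 54 macrophage identity and ribosomal genes had a nigericin EZH2 peak, although these lists were not chosen for activity after LPS and 2 of 30 NF-kB and LPS response genes, Il12b (2.88) and Ccl4 (2.59), had one. A property of this one library cannot be told apart from the treatment, because only 1 EZH2 library after nigericin was analysed here. Within the treatment, LPS cannot be told apart from nigericin, since no library had LPS alone. A signal from transcribed sequence stays open, since exon positions were not used here. Recruitment of EZH2 to interferon-inducible genes would be the biological reading, and it was not tested.

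EZH2 and p53 peaks lay together at Neat1 and at Nlrp3, outside H3K27me3. Regions called as peaks in every library were argued against, with a SIRT1 peak in 1 of 8 checks (both places in 4 lists). By the labels' names the SIRT1 libraries had other inputs, and their background was lower, which limits this check. The H3K27ac list had a peak over both places. Regions that attract reads only in the EZH2 and p53 libraries, with or without H3K27ac, or also in the inputs, were not checked. Whether a gap in the input library contributed to these peaks could not be decided. The background recovered for a peak is a local value and need not equal the input at the summit. The local background at the untreated EZH2 peaks was 3.57 at Neat1 and 5.55 at Nlrp3, above the most common value of that list (2.74). At both p53 peaks it was also above the most common value of its list (1.945). The EZH2 summits held 37 and 40 fragments and the p53 summits 24 and 41, far above these backgrounds. Backgrounds above the common value can also mean that the input was itself enriched there, and the input reads were not examined. DNA fragments with fixed ends, such as amplified product or construct DNA, cannot be told apart from binding at either gene. At Nlrp3 the gap between the edges of the untreated and nigericin peaks was within the lowest 1.48% of pairs, but the near-equal edges had been noticed first and the gaps to the p53 peak ranked 2 of only 14 and 2 of 9 pairs, while at Neat1 the gap between EZH2 and p53 ranked 4 of 14. The H3K27ac peak at Nlrp3 ended at 59549712, close to the end of the untreated EZH2 peak (59549714). Its start was further away (59547901, against 59548030). Binding of both proteins at these genes remains open and was not tested by a second library.

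Peaks on sequences outside chromosomes 1 to 19, X and Y entered no comparison and numbered 72 for untreated EZH2, 68 for nigericin EZH2, 96 for p53, 7 for H3K27ac, 7 for H3K27me3, and 91, 54, 58 and 34 for SIRT1 in Ezh2 wild-type, Ezh2 knockout, p53 wild-type and p53 knockout cells. The Fasl p53 peaks of 382 and 338 bp (the first 10.9-fold) overlapped no peak of another list, and the Rela SIRT1 peak of 574 bp (17.1-fold) overlapped no other SIRT1 peak but an H3K27ac peak of 2.83-fold. The median width over all peaks was 380 bp for p53 and 245 bp for SIRT1 in Ezh2 wild type. Most of those peaks were weaker, with a median of 8 and 4 fragments at the summit. Among the 11 p53 peaks with −log10 q of at least 5, the Fasl peaks were the shortest. The next were 394 and 396 bp long. The width at Rela was not compared with SIRT1 peaks of its strength. Whether these peaks hold construct or amplified DNA was not tested.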

How the results depend on the processing

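The settings with q of at most 0.05, at least 6 fragments, regions shared by 7 lists, whole genes and protein-coding random lists were chosen after seeing the data; the rest were planned. Of 70 alternative overlap shares of the 13 planned pairs of lists, 66 kept their direction against shifts and their side of the permutation p threshold of 0.05, 2 reversed and 2 lost it. For p53 peaks in H3K27ac the share was 18.2% with −log10 q of at least 5 and 5.08% with q of at most 0.05, both reversed against chance, and 0.710% at equal list length, no longer past the threshold; for p53 peaks in H3K27me3 it was 0% with −log10 q of at least 5, which left 11 p53 peaks. With −log10 q of at least 5, the p53 peaks over H3K27ac were those at Neat1 and Nlrp3. At a q of at most 0.05 they were the same and a place on chromosome X (38849742 to 38850246). The cause of these changes was not tested, although the stricter settings held few peaks. Of the 23 other pairs, run again with q of at most 0.05, 16 kept both, 2 reversed (nigericin EZH2 in H3K27ac, 1.45%, and p53-knockout SIRT1 in p53, 1.24%), 2 newly passed (SIRT1 in p53, Ezh2 wild type 2.01% and p53 wild type 1.67%) and 3 lost the threshold (SIRT1 in H3K27me3, Ezh2 wild type 9.24%, p53 wild type 9.44% and p53 knockout 7.74%); the cause was not tested. The other shares of the planned pairs ranged from 29.7% to 57.3% for nigericin EZH2 peaks in the untreated list, 13.8% to 26.3% for the reverse, 35.6% to 98.1% for EZH2 in H3K27me3, 0.532% to 2.17% for EZH2 in H3K27ac, 3.12% to 27.3% for p53 in EZH2, and 1.39% to 47.9% for Ezh2 wild-type SIRT1 peaks in the knockout list. Of 27 alternative values of peaks near gene ends, 23 stayed on their side, while p53 passed the threshold with −log10 q of at least 5 (36.4%) and with q of at most 0.05 (15.3%), and SIRT1 with −log10 q of at least 5 no longer passed it in the Ezh2 knockout (6.98%) and in p53 wild type (12.5%). The cause was not tested. Of 126 pairs of gene list and library, 41 stood apart from random (35 with more peaks, 6 with fewer), against 45 with windows of 5 kb, 51 with whole genes and 30 with protein-coding random lists; there were 14 with random lists matched on H3K27ac, 22 with −log10 q of at least 5 and 23 with q of at most 0.05, and the cause was not tested. Matching on H3K27ac fixes the H3K27ac count by construction. Exclusion of regions with a peak in all 9 lists was void, since 0 regions had one, and 3 regions had a peak in the 7 lists other than the histone marks. The alternatives of the p53 motif search and the split by exon and intron were not run. SIRT1 peaks of 3 or 4 fragments are near the limit of detection, so a gene without a peak is not shown to lack SIRT1. No paired analysis was possible because each group had 1 library and no test compared groups.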

Other observations

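The comparison of SIRT1 shares across Polycomb genes was chosen after the values had been seen, as were the domains named for their width. Active and repressed H3K27 states were largely apart at gene ends: 8830 genes had H3K27ac, 10366 had H3K27me3, and 752 had both, against 1833 for independent lists. The highest H3K27ac folds at gene ends were at the prostacyclin receptor gene Ptgir (11.4), Hipk2 (11.2), Spi1 (10.8), the neighbours Uhrf2 and Gldc (10.7), the lysosomal protease gene Ctsd (10.2), the cytokine gene Tnfsf12 (10.2) and Slc37a2 (10.2). The highest H3K27me3 folds were at Gas8 (23.3), where a peak of 69283 bp (chromosome 8, 123535006 to 123604288) reached from the end of the gene over the repeated 5S ribosomal RNA genes, at the MHC class I genes H2-Q10 (17.0), H2-Q1 and H2-Q2 (16.1 each), Srcin1 and Gata4 (16.6 each) and the neighbours Ctrb1 and Bcar1 (16.3). The widest H3K27ac peaks included 50002 bp on chromosome 4 (132586629 to 132636630), 42652 bp at Zmiz1 and 36623 bp at Tfeb, the lysosomal regulator gene. The widest H3K27me3 peak covered 140456 bp at the Hoxc cluster (chromosome 15, 102904914 to 103045369), followed by 85849 bp at the synaptic scaffold gene Shank2.

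Among markers of other cells of the marrow, those of lymphocytes and stroma stood apart from random lists in H3K27me3, and no list of markers stood apart in H3K27ac. Of 13 lymphocyte markers, 7 had H3K27me3 (random mean 2.71), with the B-cell factor gene Pax5 (10.9), Cd2 (7.16) and Cd3e (5.97), while Ms4a1 (5.24) and Cd79a (3.66) had H3K27ac (random mean 2.30). Of 12 stromal markers, 6 had H3K27me3 (2.49), with Cxcl12 (9.88) and Pdgfra (9.39), and 2 had H3K27ac (2.13). Of 10 erythroid markers, 5 had H3K27me3 (2.06), with the anion exchanger gene Slc4a1 (7.91) and Epor (6.45), and 0 had H3K27ac (1.77). Of 13 neutrophil markers, 3 had H3K27me3 (2.71), with the myeloperoxidase gene Mpo (6.27), and 3 had H3K27ac (Lcn2 3.71, Mmp8 2.66 and Cxcr2 2.30), against a random mean of 2.30.

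SIRT1 peaks at the 35 developmental regulators numbered 7 in Ezh2 wild type and 0 in its knockout, and 10 in p53 wild type and 1 in its knockout (random means 6.58, 2.61, 6.03 and 6.10). Most of them rested on few fragments: with at least 5 fragments the counts were 3 and 0, and 1 and 0. Across 798 protein-coding genes with EZH2 (q of at most 0.05) and H3K27me3, the share with a SIRT1 peak was 26.6% in Ezh2 wild type and 10.9% in the knockout, against 24.6% and 11.1% of all protein-coding genes, and for p53 it was 27.4% and 19.8%, against 24.3% and 24.7%. Since the wild-type shares were close to those of all genes, these shares cannot show whether SIRT1 binding at such genes is lost, and the question stays open.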
